A study of Rattus norvegicus with 115 samples.

How the data were processed

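RNA of sorted fractions of rat mammary tumours and glands was sequenced after SMARTer amplification of under 10 ng of RNA, per the labels' protocols. Tissue was digested with 2 mg/ml collagenase for 1 to 2 h, and NMU had been given at 50 mg/kg in 1 to 3 injections at an age of 35 to 53 days, per the labels, while the ages in the deposited sample table are partly younger. Gene counts were deposited as 1 table of whole numbers per gene symbol. STAR, FastQC and the rat build rn6 are named in the submitters' processing notes, without versions. The counting tool, the annotation, the filters and whether strand was used are not given in the sources used here, so overlapping or antisense genes and near-identical copies cannot be told apart in these counts. The amplification kit adds no molecular identifiers that the labels mention, so counts are not independent molecules, and bounds from counts of 0 cover counting error only.

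The count table holds 108 columns, of which 13 were matched by name to a single sample and 95 were not used. A column name gives a rat and a tumour but no fraction, so the fraction is that of the only sample in the labels with that tumour name, and no column was assigned by its values or position. In the deposited sample table the fraction and the read file name disagree for some samples, none of them among the 13 used. Columns whose tumour is listed in more than 1 fraction could not be matched, which left the comparisons named in the closing section without libraries. The labels speak of CD45, Ep and DN fractions, whereas the design text describes populations positive for EpCAM or SMA and a double negative one. Of 17455 symbols 17107 were found in the RefSeq gene table of assembly GRCr8, which was used for names only, and no coordinates are given.

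A deposited sample table gave tumour measurements. Its CD8 values are a fraction from 0 to 1, per the file headers and values, and the authors' denominator is not stated. Other deposited columns give tumour size, growth rate, time from NMU to sacrifice, a growing or stable class and a batch number, in units or by rules that the authors did not state in the sources used here. Values of a rat's tumours were averaged, since treatment was given to the rat.

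Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions, TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment over the genes tested at 0.05. The CD45 fit took all 8 vehicle and treated CD45 libraries, which share 1 estimate of the spread, and the comparison of fractions took the 4 vehicle libraries. The difference of effect took the 11 vehicle and treated libraries. Designs set for groups that no library could be tied to were fitted with the groups that had libraries. The replicate is the rat, with 1 library per rat and fraction. Where a group holds 1 library, that library is assumed to vary like the others. The SE of a log2 fold change was derived from the F statistic, as the absolute fold change over the square root of F. CPM are scaled by TMM unless stated otherwise, and log2 CPM of lists used a prior count of 2. Fold changes of genes without counts in a group are given as bounds from pooled CPM, with 3 counts as the floor. The total counts per library, 4880375 to 29727437, give a floor of 3 counts at 0.101 to 0.615 CPM.

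The designs, the other settings named first below, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 genes per direction with the largest fold change among those that passed with an average log2 CPM of at least 3, up to 4 passing members of each list, up to 4 members of a list past its own test, and 7 genes of the fractions and drug targets. Where fewer than 10 genes passed, the 10 with the smallest p were named. Provisional symbols (starting with LOC, RGD, AABR or AC0, ending in -ps or holding an Ensembl identifier) were left out of the genes with the largest change. A few genes that the rule names are not reported here. Genes given beyond it, among them the rest of the 16 called genes and members of lists adjusted over the list alone, were chosen after their values were seen. Of 30 gene lists, those with at least 4 measured members were tested by an exact two-sided permutation test of the mean log2 CPM per rat, and with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Single libraries were compared by list medians among 10000 random lists matched on expression, over genes with at least 1 CPM in the pair.

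The other settings fixed in this way were RLE scaling, no filter, a filter at 5 CPM, DESeq2 1.42.0, only the groups compared, batch as a covariate and leaving out each rat, a mean z-score in place of the list mean, and marker CPM by total counts. Limma voom, batch 3 alone, the fit of fractions with 11 libraries, list values without 1 rat, without RT1-DMa and RT1-DMb or in batch 3 and all phenotype comparisons with their alternatives were added after seeing the data. Phenotypes were compared with exact permutation tests and Fisher's exact tests in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and correlations with permutation tests.

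The edgeR step was tested on simulated data in which 100 genes were changed at each of 2 sizes. For combination against vehicle, with 11016 genes, it recovered 45% of the changes of log2 size 2 and 94% of those of size 4, with 5 false calls. For the inhibitor against vehicle (10944 genes) it recovered 46% and 93% with 10 false calls, for the combination against the inhibitor (10798 genes) 39% and 89% with 10, and for DN against CD45 (11039 genes) 0% and 47% with 4. The changed genes were drawn only from those above a set level in the reference group. Genes were simulated independently, without batches or differences in cell composition, so the shares recovered need not hold for real changes of these sizes.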

Results

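Mammary tumours were induced in rats with the carcinogen N-nitroso-N-methylurea (NMU, 50 mg/kg), and rats with tumours received vehicle, an antibody against the checkpoint ligand PD-L1, LY2157299 (galunisertib, an inhibitor of the TGF-beta receptor TGFBR1), or the antibody and the inhibitor together. Tumours were dissociated and sorted, and RNA of the fractions was sequenced. The labels list 115 samples in 3 fractions, named CD45 (leukocytes, which carry the protein encoded by Ptprc), Ep and DN. They fall under 44 rat names, and the number of rats may be lower, since glands are named apart from tumours and the deposited sample table gives some of them the number of a rat with tumours. The CD45 fraction held 12 samples of 8 vehicle rats, 7 samples of 5 rats on the TGFBR1 inhibitor, 8 samples of 5 rats on anti-PD-L1 and 8 samples of 6 rats on the combination. It also held 10 samples of 8 rats with untreated tumours, 7 mammary glands of 7 rats given NMU and 1 gland of a rat without NMU. The DN fraction held 11, 4, 8 and 8 samples of vehicle, TGFBR1 inhibitor, anti-PD-L1 and combination tumours, from 7, 2, 6 and 6 rats. The Ep fraction held 4, 4, 8 and 5 samples in the same order, from 4, 4, 6 and 4 rats, and 10 samples of untreated tumours of 8 rats.

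The gene counts of 13 libraries were tied to a sample by name. These were 9 CD45 libraries (3 vehicle, 2 TGFBR1 inhibitor, 3 combination, 1 untreated tumour), 3 libraries labelled DN (1 each of vehicle, anti-PD-L1 and combination) and 1 library labelled Ep from an untreated tumour. Total counts ran from 4880375 in the Ep library to 29727437 in the CD45 library of combination rat P23. Among the CD45 libraries the lowest total was 6674181 (vehicle rat P14). The libraries labelled DN held 25848279 (vehicle rat P10), 8304815 (anti-PD-L1 rat P38) and 8050029 counts (combination rat P23). Each treated or vehicle CD45 library came from a different rat and from a tumour classed as growing. CD45 libraries of TGFBR1 inhibitor rat P16 and combination rat P31 belonged to batch 2, the untreated CD45 library to batch 1 and the other 10 libraries to batch 3. No pair of libraries was identical, and the highest correlation between log values of a pair was 0.982.

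Leukocyte genes marked the libraries labelled CD45, and epithelial genes marked those labelled DN. Ptprc, the gene of CD45 itself, lay at a normalised read count of 1115 ± 283 CPM (SD, n = 9) in the CD45 libraries and at 10.2 ± 15.9 CPM (n = 3) in the libraries labelled DN. Cd3e, a chain of the T cell receptor complex, lay at 951 ± 483 and 4.38 ± 6.97 CPM. Epcam, an adhesion protein of epithelial cells, lay at 1782 ± 1217 CPM in the libraries labelled DN against 24.2 ± 18.0 CPM in the CD45 libraries, and the keratin Krt8 at 4869 ± 2920 against 55.4 ± 45.4 CPM. The casein Csn2, a milk protein, ranged from 12.3 to 2879 CPM in the libraries labelled DN and lay at 3.37 ± 7.95 CPM in the CD45 libraries.

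The single library labelled Ep held both epithelial and stromal transcripts. Its Epcam lay at 883 CPM, below the lowest library labelled DN (943 CPM), although scaling by total counts gave the opposite order (1389 against 1217 CPM). Its Krt8 lay at 1405 CPM. Col1a1, the main collagen of fibroblasts, lay at 1458 CPM in this library, at 254 ± 260 CPM in those labelled DN and at 5.89 ± 9.46 CPM in the CD45 libraries. The smooth muscle actin Acta2 lay at 46.9 CPM in the Ep library, 60.6 ± 49.7 CPM in the libraries labelled DN and 8.98 ± 8.55 CPM in the CD45 libraries. The endothelial gene Pecam1 lay at 23.8, 8.76 ± 6.37 and 30.1 ± 12.2 CPM in the same order. These levels were described without a test, and the count columns name the tumour but not its fraction, so the fraction is that of the only sample with that tumour name.

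**Figure D1:**
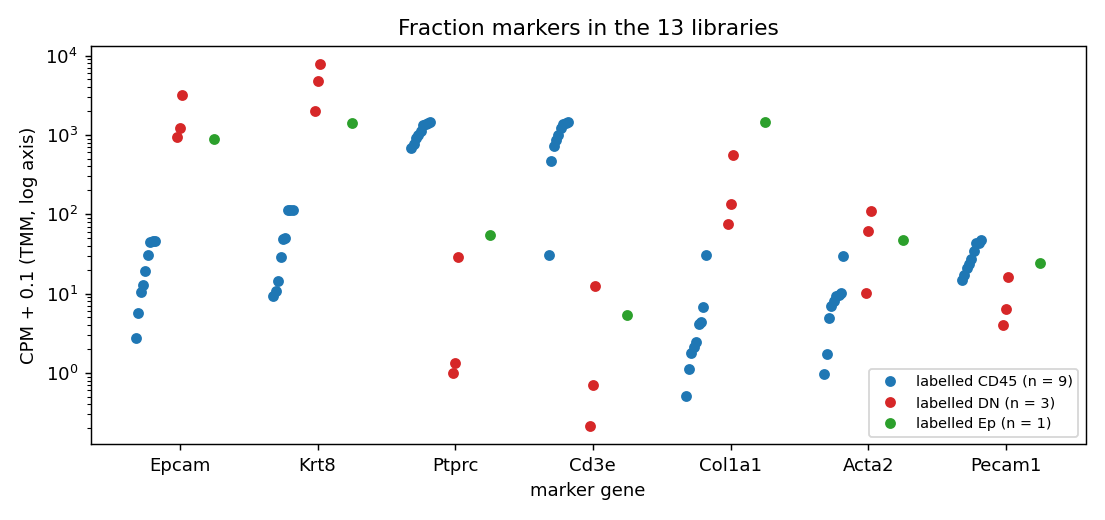
Level of 7 marker genes (horizontal axis) in 13 libraries as CPM + 0.1 on a log axis, 1 point per library, coloured by labelled fraction. Epcam lies between 943 and 3178 CPM in the 3 libraries labelled DN and at 883 CPM in the library labelled Ep, and Ptprc lies between 693 and 1460 CPM in the 9 CD45 libraries.

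What the combination did to tumour leukocytes was asked by comparing the CD45 libraries of 3 combination rats with those of 3 vehicle rats. By edgeR 16 genes fell with the combination and 0 rose, and of these only Lpl, in the adipocyte list, was a member of a fixed gene list. Pla2g2d, a secreted phospholipase of antigen-presenting cells, fell from 325 ± 275 to 7.48 ± 3.46 CPM (log2 fold change -5.43, SE 0.752, edgeR adjusted p = 0.0432). Lpl, the lipoprotein lipase that macrophages and adipocytes secrete, fell from 86.3 ± 29.9 to 3.32 ± 0.791 CPM (log2 -4.71, SE 0.586, edgeR adjusted p = 0.0257). Cfp, the complement factor properdin, fell from 866 ± 339 to 61.9 ± 36.2 CPM, and Cd59, an inhibitor of the terminal complement complex, from 466 ± 275 to 29.3 ± 0.610 CPM.

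The Fc receptor relative Fcrl2 fell from 502 ± 252 to 21.6 ± 8.51 CPM, and Fxyd2, a subunit of the sodium pump, from 246 ± 141 to 6.77 ± 0.464 CPM. Tppp3, a tubulin-binding protein, fell from 102 ± 71.8 to 6.55 ± 2.11 CPM, and the phospholipase gene Plcd3 from 32.2 ± 8.90 to 2.42 ± 0.349 CPM. The other 8 genes were Tgfb1i1 (a focal adhesion protein first found as induced by TGF-beta, log2 -3.55), Alox5ap (leukotriene synthesis, -3.23), the chemokine Ccl6 (-3.33), the myeloid signalling adaptor Card9 (-3.00), Fndc5 (-3.65), Lpcat2 (-3.15), Zfp710 (-2.56) and Rassf4 (-2.48). In 16 of the 16 genes every combination library lay below every vehicle library. Of all 11354 genes tested, 2820 (24.8%) were separated in this way in either direction, against 10% by chance for 3 against 3 libraries. The 16 genes were picked in a fit that held these same libraries, so their separation adds no support of its own.

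At an unadjusted p under 0.05 edgeR counted 2001 of the 11354 genes, 836 higher and 1165 lower, and the smallest adjusted p was 0.0219. DESeq2 called 822 genes and limma voom 15 on the same counts. The calls depended on single libraries: none passed without combination rats P23, P31 or P35 or vehicle rat P14, 10 passed without TGFBR1 inhibitor rat P16 or P19, 361 without vehicle rat P13 and 51 without vehicle rat P5. Within batch 3, where 2 combination and 3 vehicle libraries remained, edgeR called 0 genes (and 0 with batch as a covariate), while the median log2 fold change of the 16 genes was -3.57 against -3.69 over both batches. With only these 2 treatment groups in the fit edgeR called 1 gene, and with no filter on low counts 113.

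Macrophage genes lay lower as a group. All 17 measured members had fold changes below 0, and 17 of 17 passed when adjusted over the list alone (edgeR), against 0 over all genes tested. The call of the list by limma's camera was lost (adjusted p = 0.715 with an estimated correlation). Cd68, a lysosomal marker of macrophages, had a log2 fold change of -3.95 (SE 0.629), the mannose receptor Mrc1 of -4.50, the scavenger receptor Cd163 of -4.40, the complement component C1qa of -4.47 and the growth factor receptor Csf1r of -3.76. The mean log2 CPM of the list was 3.85 ± 0.414 (n = 3) against 6.93 ± 1.72 (n = 3), a difference of -3.07 that was -2.86 within batch 3 and -2.12 without vehicle rat P5. In the CD45 library of an untreated tumour, of another cohort and batch, the list mean lay below each combination library, as given under the other observations.

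Genes of MHC class II presentation, which show antigen to helper T cells, also lay lower, and limma's camera lost this call too (adjusted p = 0.715 with an estimated correlation). The list mean was 6.73 ± 1.08 against 9.31 ± 1.07, a difference of -2.58 (batch 3 -2.11), and 10 of 11 members were lower and 1 higher when adjusted over the list alone, against 0 over all genes tested. The invariant chain Cd74 lay at 5353 ± 2478 and 50823 ± 38503 CPM (log2 -3.25), RT1-Da at 1133 ± 462 and 12054 ± 10280 CPM (log2 -3.41), and Ciita, the master regulator of the class, had a log2 fold change of -3.27. RT1-Bb was the member in the other direction (log2 5.25), and it ranged from 0.632 to 762 CPM among the CD45 libraries. RT1-DMb (log2 -4.05) had no counts in the batch 2 libraries, and RT1-DMa, also among the lower members, had 5 and 6 counts there against 226 to 4302 in the CD45 libraries of batch 3. Without these 2 members the list differed by -2.02 (batch 3 -1.88). The CD45 library of an untreated tumour, of another cohort and batch, then stood at 7.92, within the range of the combination libraries (7.24 to 8.84). The dendritic cell list differed by -1.51 (batch 3 -1.07), with 3 of 11 members lower when adjusted over the list alone and 0 over all genes (limma's camera adjusted p = 0.715 with an estimated correlation).

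T cell genes made up more of the combination libraries, without passing the test. The list mean was 8.59 ± 0.264 against 6.51 ± 2.24, a difference of 2.08 (batch 3 2.03), and 0 of 17 members passed when adjusted over the list alone or over all genes. Limma's camera lost the T cell, cytotoxic and NK and regulatory T cell lists (adjusted p = 0.715 with an estimated correlation for each). Cd2 had a log2 fold change of 1.43 and Lck of 1.42, while Cd4 stood at -0.12. Without vehicle rat P5, whose library held the fewest T cell transcripts, the difference was 0.82. The cytotoxic and NK list differed by 1.87 (0.89 without rat P5, batch 3 1.72) and the regulatory T cell list by 2.36 (0.73 without rat P5, batch 3 2.35). The B cell list differed by 1.24 (batch 3 1.46, without vehicle rat P14 0.72, without combination rat P23 0.75), where Ms4a1 (CD20) and Cd79b were higher and Cd22 lower when adjusted over the list alone. The plasma cell list differed by 0.61 (batch 3 0.82, without combination rat P35 0.18) and the exhaustion and checkpoint list by 0.54 (batch 3 0.91, without rat P5 -0.21, without P13 1.03, without P35 0.24). Pdcd1, a member of the exhaustion list, had 0 counts in the batch 2 library of combination rat P31.

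Several other lists also had lower means in the combination libraries, some of them mostly through single rats. The extracellular matrix and fibroblast list differed by -1.75 (batch 3 -1.56, without vehicle rat P5 -1.01; 3 of 17 members lower adjusted over the list alone, 0 over all genes) and the luminal epithelial list by -1.30 (batch 3 -1.13, without vehicle rat P14 -0.76, without P13 -2.15; 14 of 14 members below 0). The adipocyte list differed by -1.81 (batch 3 -1.61), with Lpl past the test over all genes and 3 of 5 members adjusted over the list alone. The 3 were Lpl, which macrophages also secrete, Cfd and Fabp4, while Lipe and Retn did not fall (log2 0.35 each). Adipoq and Plin1, also listed, were not among the 5 measured, so the list does not show a loss of adipocyte transcripts. Limma's camera lost these 3 lists (adjusted p = 0.715 with an estimated correlation for each), and it called none of the lists that follow here with either correlation. The endothelial list differed by -1.07, with 4 of 11 members lower adjusted over the list alone, although Pecam1 had a log2 fold change of 0.72. Smooth muscle and pericyte genes differed by -1.12 (without rat P14 -0.31, without P13 -1.71). Inflammatory cytokine genes differed by -1.33 (without rat P5 -0.69, without combination rats P23 and P35 in turn -0.78 and -2.03) and milk and alveolar genes by -0.78 (batch 3 -0.29, without rat P14 -0.32, without P23 and P35 in turn -0.50 and -1.54). The cytokine list holds Tnf, which had at most 2 counts in the earlier batches, combination rat P31 among them. In the CD45 libraries of batch 3 it had at least 111 counts, so the cytokine difference partly mixes batches. The neutrophil list mean was 1.29 ± 0.311 against 2.29 ± 1.32, and the difference was -0.29 without rat P14 and -1.60 without P5.

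For each of the other lists the difference moved by over 1.5 times or turned its direction when a single rat was left out. TGF-beta response genes differed by -0.24 (batch 3 -0.090), which was 0.19 without combination rat P23, -0.83 without combination rat P35, -0.43 without vehicle rat P14 and -0.061 without vehicle rat P5. Epithelial-mesenchymal transition genes differed by -0.63 (without rat P13 -0.96, without P14 -0.37) and proliferation genes by -0.40 (batch 3 -0.59, without vehicle rat P13 -0.17). MHC class I presentation differed by 0.031 (batch 3 0.10, from -0.14 without rat P14 to 0.22 without P5) and type I interferon response by -0.042 (batch 3 0.073, without rat P14 -0.15). Interferon-gamma response differed by -0.42 (from -0.81 without rat P14 to 0.052 without P5) and hypoxia by -0.17 (batch 3 -0.074, from -0.33 without rat P13 to 0.11 without P5). Dissociation stress differed by 0.12 (batch 3 0.22, without combination rat P35 -0.081), hormone response by -0.64 (without rats P23 and P35 in turn -0.28 and -1.12) and basal epithelial genes by -0.58. Without vehicle rat P14 these 3 differences were -0.25, -0.027 and 0.18, and without vehicle rat P13 they were 0.44, -1.40 and -1.26. Mast cell and eosinophil genes differed by 0.13 (batch 3 0.58, without rat P5 -0.31, without P23 -0.45) and skeletal muscle genes by -0.31 (from -0.83 without rat P5 to 0.038 without P14). Of the single genes fixed in advance, Ptprc lay at 1311 ± 67.2 and 759 ± 113 CPM (log2 0.79, edgeR adjusted p = 0.191). Acta2 (log2 -1.80), Epcam (-1.43), Tgfb1 (-0.94), Cd274, which encodes PD-L1 (0.61), Pdcd1, which encodes PD-1 (0.55), and Tgfbr1 (-0.38) did not pass either. Pdcd1 had 0 counts in the CD45 libraries of batches 1 and 2, which are combination rat P31, inhibitor rat P16 and the untreated rat, and 3 to 520 in those of batch 3, so its fold changes in the CD45 comparisons mix batches.

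List means of 3 against 3 rats cannot give an exact two-sided permutation p below 0.1, so none of the 29 lists could pass, and the smallest adjusted exact p was 0.414. Limma's camera with a preset correlation of 0.01 called 9 lists: macrophage, MHC class II, T cell, cytotoxic and NK, regulatory T cell, dendritic cell, extracellular matrix, luminal and adipocyte. Each of the 9 was lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation in limma's camera).

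**Figure D2:**
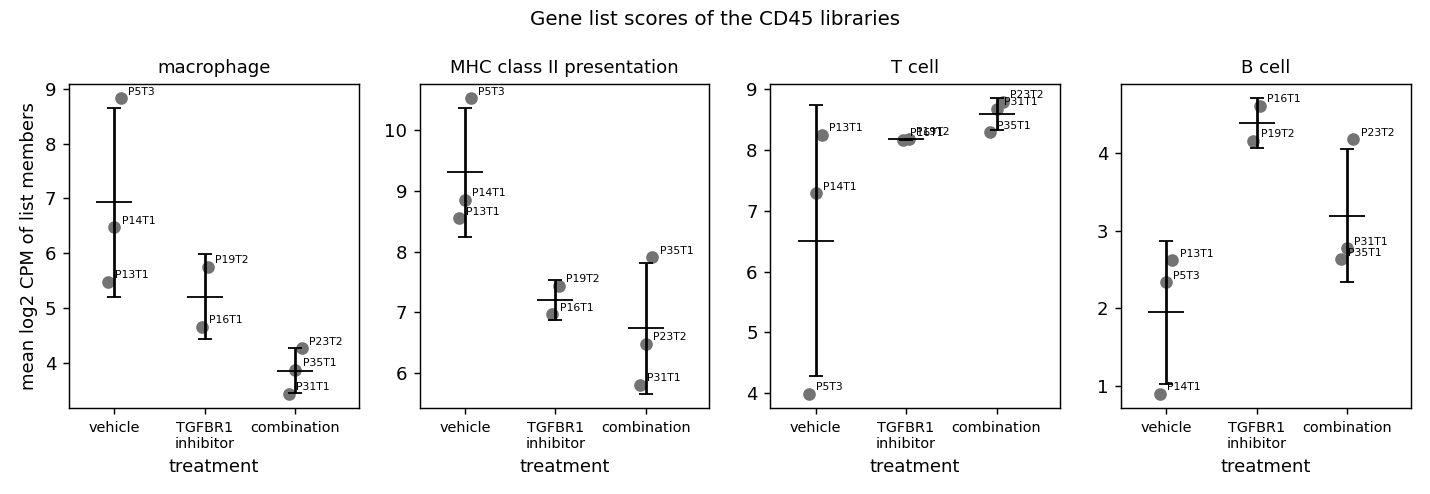
Mean log2 CPM of the members of 4 gene lists (vertical axis) in the CD45 libraries of vehicle, TGFBR1 inhibitor and combination rats, 1 labelled point per library, with the group mean and SD as a bar. The macrophage mean is 6.93 with vehicle, 5.20 with the inhibitor and 3.85 with the combination, and the T cell means are 6.51, 8.18 and 8.59.

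The effect of the TGFBR1 inhibitor alone on leukocytes was asked with the CD45 libraries of 2 treated and 3 vehicle rats. No single gene passed, and the 10 genes with the smallest p are given here. Tgfb1i1 lay at 15.7 ± 5.16 CPM against 104 ± 31.6 CPM with vehicle (log2 -2.73, SE 0.412, edgeR adjusted p = 0.595), and Fxyd2 at 21.8 ± 0.489 against 246 ± 141 CPM (log2 -3.50). Fcrl2 (-2.73), Cd59 (-2.43), Card9 (-1.97), Zfp710 (-1.79) and the selenoprotein Selenom (-2.99) also lay lower. Egln3, an oxygen-sensing hydroxylase, lay at 110 ± 1.32 against 31.2 ± 10.9 CPM (log2 1.82), the ectoenzyme Cd38 at 103 ± 38.5 against 37.7 ± 2.38 CPM (1.45), and Hps6 at log2 1.68.

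B cell genes lay higher with the inhibitor, with a list mean of 4.39 ± 0.320 (n = 2) against 1.95 ± 0.922 (n = 3). Limma's camera lost this list and the MHC class II, macrophage, proliferation, T cell, cytotoxic and NK, regulatory T cell, mast cell, type I interferon and extracellular matrix lists (adjusted p = 0.586 with an estimated correlation for each). The difference was 2.43 (batch 3 2.21, with 1 inhibitor library), and 4 of 12 members were higher and 1 lower when adjusted over the list alone, against 0 over all genes. MHC class II genes differed by -2.11 (batch 3 -1.88) and by -1.34 without RT1-DMa and RT1-DMb (batch 3 -1.78), with 7 of 11 members lower adjusted over the list alone and 0 over all genes. Macrophage genes differed by -1.72 (batch 3 -1.17, without vehicle rat P5 -0.77) with 17 of 17 members below 0 and 0 passing over the list alone. Proliferation genes differed by 0.74 (batch 3 0.44), with 19 of 20 members above 0. The T cell list differed by 1.67, the cytotoxic and NK list by 2.07 and the regulatory T cell list by 2.13, which without rat P5 became 0.41, 1.08 and 0.51 (T cell 2.54 without vehicle rat P13). Within batch 3 these differences were 1.68, 1.09 and 2.22, and each batch 3 value here is also the value without inhibitor rat P16. Mast cell and eosinophil genes differed by 1.56 (batch 3 0.33), type I interferon response by 0.64 (batch 3 0.10), and extracellular matrix genes by -1.18 (batch 3 -1.17, without rat P5 -0.43, without P13 -1.85). Without inhibitor rat P19 the mast cell and interferon differences were 2.79 and 1.19. TGF-beta response differed by -0.19 (batch 3 -0.069), which was -0.0021 without rat P5, -0.37 without P14 and -0.30 without P19. The adipocyte list differed by -0.96 (batch 3 -1.11), the endothelial list by -0.80 (batch 3 -0.47) and the plasma cell list by 0.61 (batch 3 0.83, without inhibitor rat P19 0.39), with 0 members past either adjustment and, like B cell and MHC class II genes, the smallest exact p that 2 against 3 rats allow.

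EdgeR called 0 of 11354 genes here, with 926 at an unadjusted p under 0.05 (380 higher, 546 lower), DESeq2 called 84 and limma voom 0, and without vehicle rat P13 edgeR called 1. Ptprc (log2 0.39), Acta2 (-1.07), Tgfb1 (-0.62), Tgfbr1 (-0.37), Pdcd1 (-0.44), Epcam (-0.11) and Cd274 (0.08) did not pass. With 2 against 3 rats the smallest possible exact p is 0.1 and the smallest adjusted exact p over the lists was 0.58. Limma's camera called 10 lists with the preset correlation and 0 with an estimated one.

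Whether adding anti-PD-L1 to the inhibitor changed leukocytes was asked by setting the 3 combination libraries against the 2 inhibitor libraries. Proliferation genes lay lower with the combination, with a list mean of 4.64 ± 0.329 against 5.79 ± 0.432 (difference -1.15, batch 3 -1.03) and 20 of 20 members below 0. Of these, 0 passed when adjusted over the list alone or over all genes, and limma's camera lost the list (adjusted p = 0.529 with an estimated correlation). Batch 3 held 1 inhibitor library, that of rat P19, so each batch 3 value of this comparison rests on it. The mitotic regulator Cdc20 lay at 20.1 ± 1.26 against 60.5 ± 15.5 CPM (log2 -1.59) and Rrm2, a subunit of ribonucleotide reductase, at 22.4 ± 1.31 against 60.2 ± 6.11 CPM (log2 -1.43). Lpl lay at 3.32 ± 0.791 against 34.1 ± 29.1 CPM (log2 -3.37), the haem oxygenase Hmox1 at 25.4 ± 20.6 against 180 ± 72.4 CPM (-2.82) and the secreted phosphoprotein Spp1 at 35.0 ± 4.52 against 142 ± 12.8 CPM (-2.02). Gapt (-2.58), Tppp3 (-2.29), Plcd3 (-1.88), Arhgap11a (-1.56) and the water channel Aqp1 (0.0110 ± 0.0190 against 1.92 ± 1.22 CPM) completed the 10 genes with the smallest p, none of which passed.

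Fold changes were below 0 in 17 of 17 macrophage genes (difference -1.35, batch 3 -1.69) and in 12 of 12 B cell genes (-1.19, batch 3 -0.75). Of either list 0 members passed when adjusted over the list alone or over all genes. Limma's camera lost both lists (adjusted p = 0.529 with an estimated correlation for each). Luminal epithelial genes differed by -1.15 (batch 3 -0.31), dendritic cell genes by -1.20 (batch 3 -0.36), neutrophil genes by -1.25 (batch 3 -0.53), adipocyte genes by -0.85 (batch 3 -0.50) and extracellular matrix genes by -0.58 (batch 3 -0.39). Type I interferon response differed by -0.69 and by -0.025 within batch 3, and mast cell and eosinophil genes by -1.43, which was 0.25 within batch 3. MHC class II genes differed by -0.47 (batch 3 -0.24, without combination rat P31 -0.00088, without inhibitor rat P19 -0.23, without combination rat P35 -1.05). Without RT1-DMa and RT1-DMb the class II difference was -0.68 (batch 3 -0.097). Hypoxia genes differed by -0.35 (batch 3 -0.29) and dissociation stress genes by 0.42 (batch 3 0.07, and -0.026 without inhibitor rat P16), while T cell genes differed by 0.41. Without inhibitor rat P16 the luminal difference was -0.48, the dendritic cell one -0.80, the neutrophil one -0.35, that of type I interferon -0.14, that of mast cells -0.20 and that of MHC class II -0.70. Without inhibitor rat P19 the macrophage difference was -0.80, and the luminal, neutrophil, type I interferon, mast cell and dissociation stress ones were -1.82, -2.16, -1.23, -2.66 and 0.87. Without combination rat P35 the dendritic cell and dissociation stress differences were -1.86 and 0.22, and without combination rat P31 the dendritic cell and matrix differences were -0.77 and -0.38.

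EdgeR called 0 of 11354 genes, with 258 at an unadjusted p under 0.05 (40 higher, 218 lower). DESeq2 called 2, Lpl and Hmox1, and limma voom 0. Ptprc (log2 0.40), Epcam (-1.32), Acta2 (-0.74), Cd274 (0.53), Tgfb1 (-0.31), Pdcd1 (0.99) and Tgfbr1 (-0.014) did not pass. Limma's camera called 13 lists with the preset correlation and 0 with an estimated one (adjusted p = 0.529 with an estimated correlation for the proliferation, macrophage, B cell, luminal, dendritic, neutrophil, adipocyte, type I interferon and mast cell lists, and 0.655 for the other 4). The smallest adjusted exact permutation p over the lists was 0.669.

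The identity of the DN fraction was asked by comparing the library labelled DN of vehicle rat P10 with the CD45 libraries of 3 other vehicle rats. With 1 library labelled DN the difference has no replicate check on that side, so the values and counts describe this library and not the fraction. It carried milk, other epithelial and matrix transcripts, and T cell and MHC class II genes lay lower in it. The milk proteins Csn3 (log2 8.90), Lalba (8.29) and Csn1s1 (7.37) were higher, as were the tight junction gene Cldn4 (8.66) and the epithelial transcription factor Ehf (8.69). Csf3, the granulocyte growth factor G-CSF, had a log2 fold change of 13.19 from 44596 counts against 5 in the CD45 libraries. Genes without any count in the 3 CD45 libraries included Rasgef1c, at least 605-fold higher, the phosphate transporter Slc34a2, at least 572-fold higher, Dlx5 (at least 467-fold), Gldn (416), Ror1 (379), Apod (360) and Tacr1 (353).

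Many leukocyte genes lay far lower in this library. Ptprc was lower by a log2 fold change of -9.34. Several genes of leukocyte signalling and the cytoskeleton had no count at all and were at least 2112-fold lower (Lpxn), 1921-fold lower (Nckap1l), 1787-fold lower (Il21r), 1591-fold lower (Hcls1), 1331-fold lower (Arhgap15), 1200-fold lower (Hcst) and 1137-fold lower (Arhgap25). The bounds take 3 counts as the floor of the library, or of the CD45 libraries together, and cover counting error only. The T cell coreceptor genes Cd8a and Cd8b were at least 977-fold and 368-fold lower, Klrk1 449-fold, the chemokine receptor Cxcr2 545-fold and Flt3 218-fold.

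By list, 14 of 14 luminal genes, 8 of 10 milk genes, 14 of 21 extracellular matrix genes and 7 of 17 TGF-beta response genes were higher when adjusted over the list alone, against 2, 4, 4 and 4 over all genes. Matrix genes included Fbn1 (log2 6.71), Loxl1 (5.14) and Col3a1 (6.39), and TGF-beta response genes included Thbs1 (7.03), the latent TGF-beta binding proteins Ltbp1 (7.49) and Ltbp2 (8.30), and Ccn1 (7.71). Of 22 type I interferon genes, 9 were higher over the list alone and 4 over all genes: Rsad2 (9.70), Oasl (5.83), Ifih1 (3.65) and Cmpk2 (2.63). Lcn2 (7.31), Kit (6.84) and Sdc1 (2.85), listed under neutrophils, mast cells and plasma cells, are also made by epithelial cells and were higher. Of 4 erythroid genes 3 were higher over the list alone and 0 over all genes, and of 12 dissociation stress genes 4 and 0.

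All 17 T cell genes, 11 of 11 MHC class II genes, 11 of 16 cytotoxic genes, 8 of 8 checkpoint genes, 6 of 7 regulatory T cell genes, 9 of 11 dendritic cell genes and 5 of 11 B cell genes were lower when adjusted over the list alone. Over all genes the numbers were 2, 1, 1, 1, 0, 2 and 1. They included RT1-DOb (log2 -9.89), Cd244 (-6.45), Cd22 (-5.76) and the lectin Clec10a (-11.54). Of 17 macrophage genes 1, Lyve1 (-7.69), was lower by either adjustment, with log2 fold changes of the list from -12.56 to 0.998 (median -6.07). Proliferation genes were lower in 12 of 20 members over the list alone and 3 over all genes, namely Birc5 (-4.29), Ccnb1 (-3.92) and Ube2c (-4.19). The chemokines Ccl3 (-6.93) and Ccl4 (-7.78), Il1rl1 (-6.55), Gbp4 (-5.98) and Socs1 (-4.35) were lower.

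The higher and lower genes are those past edgeR's threshold if the lone library varies like the CD45 libraries, which could not be checked. On that assumption edgeR counted 510 of 12092 genes (279 higher, 231 lower), with 2953 at an unadjusted p under 0.05. The count was 0 without vehicle rat P14 and 1611 without vehicle rat P5, and DESeq2 called 2284 and limma voom 1124. A fit of all 11 treated and vehicle libraries called 2637. Epcam (log2 6.62), Tgfb1 (-4.95), Cd274 (-2.51), Acta2 (-0.73) and Tgfbr1 (0.24) did not pass, and Acta2 was at 3.07 and Tgfbr1 at -0.13 in the fit of 11 libraries. Pdcd1 had no count in the library labelled DN (at least 74.0-fold lower) and did not pass.

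Whether the combination acted differently on the fractions was asked through the difference of its effect between CD45 and DN. With 1 library labelled DN per treatment the spread between such tumours was not measured, so the values describe these libraries and cannot show whether treatments differ. Leukocyte genes were present in the combination library labelled DN (rat P23) and nearly absent from the vehicle one (rat P10), while they differed less between the CD45 groups. Hcls1 lay at 0 CPM in the vehicle and 9.37 CPM in the combination library labelled DN, and at 206 ± 41.3 and 160 ± 0.872 CPM in the CD45 libraries. Nckap1l lay at 0 and 31.7 CPM against 247 ± 77.1 and 238 ± 68.2 CPM, and Lpxn at 0 and 27.5 CPM against 274 ± 98.1 and 481 ± 56.0 CPM. The macrophage genes Clec4a3 (0 and 16.6 CPM) and Tifab (0 and 17.9 CPM) went the other way in the CD45 libraries, at 293 ± 286 and 15.1 ± 2.79 CPM and at 104 ± 87.3 and 7.76 ± 4.08 CPM.

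Rgs18 (0 and 4.11 CPM), Adgrg5 (0 and 7.55 CPM) and Parvg (0 and 9.85 CPM) had the same order in the libraries labelled DN. The difference of effect was -3.72 on the log2 scale for Ptprc and -8.13 for RT1-DOb. In the other direction were the nuclear receptor partner Nrip1 (3.87), the peptidase inhibitor Pi16 (3.72) and the galactosyltransferase B4galt1 (3.42). Nrip1 lay at 236 CPM in the vehicle and 28.9 CPM in the combination library labelled DN. Adjusted over the list alone, 14 of 18 macrophage genes, 7 of 11 MHC class II genes and 9 of 20 proliferation genes had a lower effect in CD45, and 4 of 23 type I interferon genes a higher one. Over all genes only RT1-DOb of these passed.

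If the libraries labelled DN vary like the CD45 libraries, which could not be checked, edgeR counted 46 of 12871 genes (3 higher, 43 lower; 1420 at an unadjusted p under 0.05), DESeq2 530 and limma voom 0, and edgeR with batch as a covariate 5. The count was 3 without rat P31, 16 without P35, 1 without P16, 1 without P19, 4 without P14, 93 without P13 and 128 without P5. Acta2 (-5.21), Cd274 (1.02), Tgfbr1 (0.96), Tgfb1 (-0.63) and Epcam (0.34) did not pass.

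Pairs of single libraries have no replicate check, so they were described by the median log2 ratio of each list and its percentile among 10000 random lists of like expression, which describes these libraries and not the conditions. The library labelled Ep (batch 3) held more matrix transcripts than the CD45 library of another untreated rat (batch 1), with a median log2 ratio of 7.07 (percentile 100), more luminal (4.85, percentile 100), milk (4.59, percentile 99.9) and TGF-beta response transcripts (2.85, percentile 100). Its T cell (-6.58, percentile 0) and regulatory T cell transcripts (-7.55, percentile 0) were fewer. Macrophage transcripts were more abundant in the Ep library (1.71, percentile 99.9).

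Between libraries labelled DN, that of anti-PD-L1 rat P38, from a stable tumour, held fewer matrix (-3.17, percentile 0), inflammatory cytokine (-2.75, percentile 0) and interferon-gamma transcripts (-1.87, percentile 0) than that of vehicle rat P10, from a growing tumour. It held more smooth muscle transcripts (percentile 100; list means 4.15 and 3.69 log2 CPM) and more proliferation transcripts (0.68, percentile 99.5), and its luminal median was -0.48. The combination library of rat P23 held more T cell (4.55), macrophage (3.55), dendritic cell (3.39), MHC class II (2.83), smooth muscle (2.68) and proliferation transcripts (1.83) than the vehicle library, each at percentile 100. Its inflammatory cytokine (-4.26), matrix (-2.01), luminal (-1.81) and TGF-beta response medians (-1.42) were at percentile 0.

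How treatment affected tumour growth was described from the deposited values of 43 tumours of 28 rats, averaged per rat. These comparisons were set up after the group means had been seen. Growth rate, in a unit that the deposited table does not state, was 6.40 ± 4.37 with vehicle (n = 9 rats), 8.73 ± 12.3 with the inhibitor (n = 5), 2.34 ± 2.04 with anti-PD-L1 (n = 7) and 3.49 ± 1.60 with the combination (n = 7). Anti-PD-L1 rats differed from vehicle rats by -4.06 (exact two-sided permutation p = 0.0427, adjusted 0.954), with 7 of 7 rats below the vehicle mean. The difference was -2.24 in batch 2 and -4.09 in batch 3. Combination rats differed from vehicle rats by -2.91 (exact permutation p = 0.122), again with 7 of 7 below the vehicle mean, and by -1.48 in batch 2 and -3.65 in batch 3. The vehicle median was 5.43, so most vehicle rats lay below the vehicle mean too. Inhibitor rats differed by 2.33 (exact permutation p = 0.685), which was 3.65 in batch 2, -1.63 in batch 3 and -2.98 without rat P16.

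The combination differed from anti-PD-L1 by 1.15 (exact permutation p = 0.253; batch 2 0.766, batch 3 0.438) and from the inhibitor by -5.24 (exact permutation p = 0.303; batch 2 -5.12, batch 3 -2.02, without rat P16 0.0736). Growth rate was equal to tumour size in 3 tumours (1 of inhibitor rat P22 and 2 of vehicle rat P5), and without them the differences from vehicle were -3.03 for anti-PD-L1 and -1.87 for the combination. Tumours were classed as stable in 2 of 14 cases with vehicle, 2 of 8 with the inhibitor, 4 of 9 with anti-PD-L1 and 4 of 11 with the combination (Fisher's exact p against vehicle 0.602, 0.162 and 0.35, which takes tumours of 1 rat as independent). Per rat the mean stable share was 0.167, 0.3, 0.5 and 0.238 in the same order (exact permutation p against vehicle 0.73, 0.166 and 0.792). This class followed the growth rate without overlap, at most 1.97 in 12 stable tumours and at least 2.36 in 30 growing ones. The rule for the class is not stated and may itself use the growth rate, so the stable share may not be a separate measure.

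The CD8 fraction, whose denominator is not stated, was 0.0765 ± 0.0849 with vehicle (n = 8 rats), 0.0674 ± 0.0553 with the inhibitor (n = 5), 0.101 ± 0.131 with anti-PD-L1 (n = 7) and 0.0414 ± 0.0282 with the combination (n = 4). Exact permutation p against vehicle was 0.878, 0.645 and 0.547. The differences from vehicle were -0.00909 for the inhibitor (batch 2 -0.0299, batch 3 -0.0266, without vehicle rat P7 0.0195), 0.0241 for anti-PD-L1 (batch 2 -0.00777, batch 3 0.0163, without rat P28 -0.0225) and -0.0351 for the combination (batch 2 -0.0465, batch 3 -0.0200, without vehicle rat P7 -0.00652). Tumour size was 24.2 ± 12.5, 21.6 ± 13.8, 14.6 ± 10.4 and 22.7 ± 12.1 and time from NMU to sacrifice 110 ± 32.3, 110 ± 42.9, 120 ± 32.6 and 126 ± 57.0 in the same order, both in units that are not stated. Of 25 comparisons over 5 measures, 1 had an unadjusted exact p under 0.05 and 0 passed after adjustment (smallest adjusted p 0.954).

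Growth rate and tumour size went together over all rats, but the rule for growth rate is not stated and may itself use tumour size. Over 28 rats growth rate and tumour size had r = 0.594 (permutation p = 0.00018, adjusted 0.00054) and rho = 0.816 (permutation p = 1e-05, the smallest that the resamples can give, adjusted 3e-05). Without the 2 rats farthest from the median growth rate r was 0.782. Without tumours whose growth rate equals their size r was 0.639 and rho 0.880. Within batch 2 r was 0.656 (19 rats) and within batch 3 0.319 (18 rats, permutation p = 0.198), where rho was 0.461 (permutation p = 0.0562). Without the 2 farthest rats r was 0.909 in batch 2 and 0.723 in batch 3. Growth rate and CD8 fraction had r = -0.156 (permutation p = 0.385, adjusted 0.385) and rho = -0.147 (permutation p = 0.491, adjusted 0.736) over 24 rats, with r = -0.217 in batch 2 and 0.117 in batch 3 and r = -0.358 without the 2 farthest rats (batch 2 -0.520, batch 3 0.104). Tumour size and CD8 fraction had r = -0.312 (permutation p = 0.132, adjusted 0.199) and rho = -0.0635 (permutation p = 0.769, adjusted 0.769), with r = -0.476 in batch 2, 0.151 in batch 3 and -0.344 without the 2 farthest rats. The family held 3 relations.

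**Figure D3:**
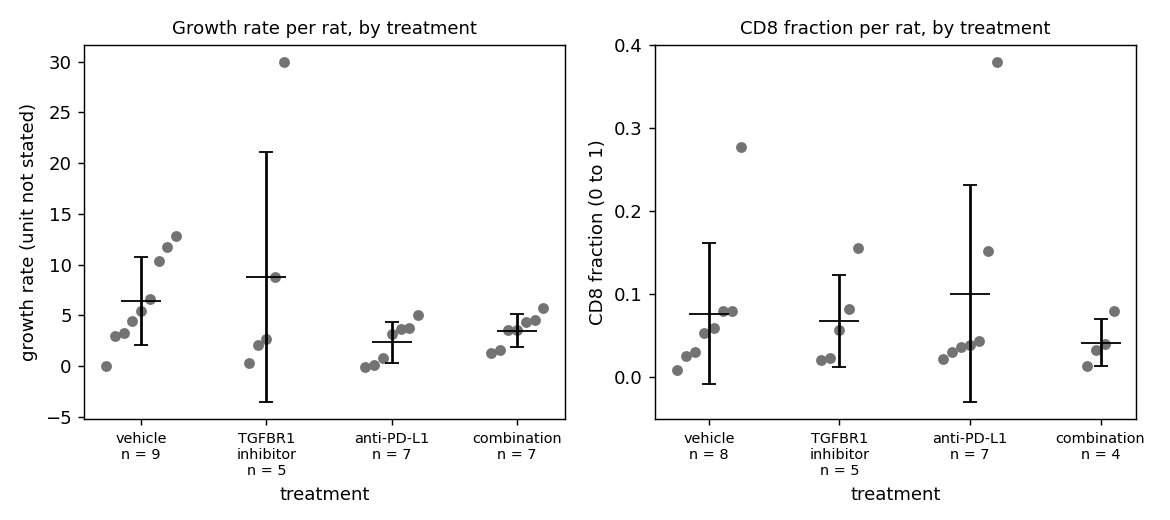
Growth rate (left, unit not stated) and CD8 fraction (right, 0 to 1) by treatment, 1 point per rat, with the mean and SD as bars. All 7 anti-PD-L1 rats and all 7 combination rats lie below the vehicle mean growth rate of 6.40, and 1 inhibitor rat lies at 30. Most vehicle rats also lie below that mean (vehicle median 5.43).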

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

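The phenotype groups below and the values of rat P23 were looked at only after results had been seen, whereas the test of the difference between fractions was planned. In 3 of 16 groups of rats the most extreme value lay further from its neighbour than the limit of Dixon's test for a group of that size. That limit is passed in about 1 in 20 groups by chance only if the values are normally distributed. The flagged groups were skewed, for example with a mean of 8.73 and a median of 2.62 for growth rate with the inhibitor. Whether 3 of 16 is more than chance gives therefore cannot be told. The growth rate of inhibitor rat P16 was 30 and the next value 8.76, a gap of 0.714 of the range. The CD8 fraction of vehicle rat P7 was 0.277 and the next 0.0800 (gap 0.732 of the range). The CD8 fraction of anti-PD-L1 rat P28 was 0.380 and the next 0.152 (gap 0.637 of the range).

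For the difference of the combination's effect between the CD45 libraries and those labelled DN, edgeR counted 46 genes, 3 higher and 43 lower in CD45, and limma voom 0. There was 1 library labelled DN per treatment, so its spread was taken from the CD45 libraries, and a difference between treatments was not tested with replicates. The count was 3 without rat P31, 16 without P35, 1 without P16 or P19, 4 without P14, 93 without P13 and 128 without P5. Ptprc lay at 28.4 CPM in the combination library labelled DN and at 1.23 CPM in the vehicle one, against 1352 ± 71.4 and 778 ± 120 CPM in CD45. In rat P23 the library labelled DN differed from the CD45 library, of another tumour, by -6.34 in the T cell list and by 1.58 in the macrophage list (mean log2 CPM).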

How the results depend on the processing

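Limma voom, batch 3 alone, the fit of 11 libraries, all phenotype alternatives and the values of lists without 1 rat, without RT1-DMa and RT1-DMb or in batch 3 were added only after the results were seen, and the other alternatives were planned. Of the alternatives for results that answer a comparison, 160 were rated the same, 18 weaker, 17 stronger and 7 reversed. For single genes, single lists and the other phenotype values these numbers were 1799, 174, 24 and 77. For counts of called genes or lists, the same meant a like count, whatever the genes and their directions. For single genes and phenotypes it meant an unchanged direction and side of the threshold, and for single lists an unchanged direction alone. No phenotype comparison had passed, so those rated the same had only stayed short of the threshold. Over all lists in the 3 CD45 comparisons, including those given no value in the text for a comparison, 65 of 551 values without 1 rat or in batch 3 turned direction. The cause was not tested unless given. Calls for combination against vehicle in CD45 were 16 and became 113 without a filter, 822 with DESeq2, 1 with only these groups, 0 in batch 3, 0 with batch as a covariate and 0 to 361 without 1 rat. The inhibitor against vehicle gave 0, and 84 with DESeq2 and 0 to 1 without 1 rat, and combination against inhibitor 0, and 2 with DESeq2. DN against CD45 gave 510, and 2284 with DESeq2, 1124 with limma voom, 2637 with 11 libraries and 0 to 1611 without 1 rat. The difference of effect gave 46, and 29 with RLE, 530 with DESeq2, 0 with limma voom, 5 with batch as a covariate and 1 to 128 without 1 rat. Lists past the test were 0 by exact test, and 10, 9 and 13 by camera with a preset correlation for inhibitor against vehicle, combination against vehicle and combination against inhibitor.

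Directions turned only in values that had not passed. For the inhibitor against vehicle, batch 3 alone gave log2 0.19 for Tgfbr1, 0.54 for Pdcd1 and -0.14 for Cd274, batch as a covariate 0.57 for Pdcd1 and -0.18 for Cd274, and limma voom 0.44 for Epcam. For combination against inhibitor limma voom gave 0.10 for Tgfbr1, and batch 3 gave 0.25 for the mast cell list. For combination against vehicle batch 3 gave 0.073 for the type I interferon list. With 11 libraries DN against CD45 gave 3.07 for Acta2 and -0.13 for Tgfbr1. Without 1 rat, inhibitor against vehicle ranged from -0.98 to 0.24 for Tgfb1, -1.32 to 0.19 for Tgfbr1, -10.02 to 0.74 for Pdcd1, -0.24 to 0.60 for Cd274 and -1.34 to 0.55 for Epcam. For lists, combination against vehicle ranged from -0.83 to 0.19 for TGF-beta response, -1.26 to 0.18 for basal epithelial, -0.15 to 0.073 for type I interferon, -0.81 to 0.052 for interferon-gamma, -0.14 to 0.22 for MHC class I, -0.21 to 1.03 for exhaustion, -0.45 to 0.58 for mast cell, -0.33 to 0.11 for hypoxia, -0.25 to 0.44 for dissociation stress and -0.83 to 0.038 for skeletal muscle genes. Combination against vehicle ranged from -0.13 to 1.73 for Pdcd1, combination against inhibitor from -0.62 to 0.92 for Tgfbr1 and from -0.026 to 0.87 for the dissociation stress list, and DN against CD45 from -1.03 to 0.038 for Acta2.

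Among phenotypes, growth rate for inhibitor against vehicle was -1.63 in batch 3, and CD8 fraction for anti-PD-L1 against vehicle -0.00777 in batch 2 and for combination against inhibitor 0.00663 in batch 3. In batch 2 tumour size was 0.4 for inhibitor against vehicle and -3.37 for combination against inhibitor (-0.410 without tumours whose growth rate equals their size), and the stable share -0.2 and 0.217 (0.114 per tumour). Without 1 rat, growth rate ranged from -2.98 to 4.46 for inhibitor against vehicle and -7.37 to 0.0736 for combination against inhibitor. CD8 fraction ranged from -0.0311 to 0.0195 for inhibitor and -0.0225 to 0.0527 for anti-PD-L1 against vehicle. Tumour size ranged from -7.20 to 1.30 for inhibitor and -4.40 to 1.34 for combination against vehicle and -2.81 to 5.69 for combination against inhibitor. Time ranged from -13.1 to 13.9 for inhibitor, -0.944 to 16.96 for anti-PD-L1 and -2.94 to 23.6 for combination against vehicle, -12.5 to 16.7 for combination against anti-PD-L1 and -3.03 to 28.9 against inhibitor. The stable share ranged from -0.0417 to 0.237 for inhibitor and -0.0556 to 0.176 for combination against vehicle, and -0.189 to 0.113 for combination against inhibitor.

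No paired analysis was possible because the groups compared share fewer than 2 rats with a usable library. Not run, for lack of usable libraries, were CD45 tumour against gland with its alternatives, DN against Ep in vehicle tumours, Ep comparisons of treatments, CD45 anti-PD-L1 comparisons, DN inhibitor comparisons and the differences of effect for the inhibitor and for anti-PD-L1. Ep against CD45 in untreated tumours and DN anti-PD-L1 and combination against vehicle or each other had 1 library per group and no test. Fits of every tumour and duplicateCorrelation were not run, since each rat has 1 library per fraction. Depth limits genes with few counts, and a count of 0 allows up to 0.101 CPM in the deepest library and 0.615 CPM in the shallowest.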

Other observations

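The tests of explanations in this part were chosen only after the results were seen, and the first 2 paragraphs give values without a test. In the CD45 library of an untreated tumour, of another cohort and of batch 1, macrophage and MHC class II transcripts lay below those of each vehicle library. Its macrophage list stood at 3.13 (mean log2 CPM), against 3.35 to 4.08 in the 3 combination libraries and 5.10 to 8.44 in the 3 vehicle libraries. Its MHC class II list stood at 6.04, against 5.89 to 7.99 and 8.63 to 10.62, a value lowered by RT1-DMb (0 counts in it) and RT1-DMa (1 count), and without these at 7.92, against 7.24 to 8.84 and 9.22 to 11.11. Its T cell list stood at 8.16, against 8.37 to 8.89 and 4.08 to 8.33, and its B cell list at 1.05, against 2.71 to 4.28 and 0.97 to 2.703, so its B cell list lay within the vehicle range.

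Between the libraries labelled DN of combination rat P23 and anti-PD-L1 rat P38, the former held more MHC class II (median log2 ratio 2.99, percentile 100), macrophage (2.63, percentile 100), proliferation (1.34, percentile 100) and basal epithelial transcripts (1.20, percentile 100). Matrix transcripts were also more abundant in it (1.45, percentile 100). It held fewer luminal (-0.86, percentile 0) and dissociation stress transcripts (-1.14, percentile 0). The percentiles are among 10000 random lists and describe these libraries, not the treatments.

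The 16 genes lower in the CD45 libraries of combination rats hold 1 member of a fixed list, Lpl of the adipocyte list, and 0 of the macrophage, MHC class II and dendritic cell lists. This does not set the 16 apart from these cells, since the lists are short and leave out genes such as Pla2g2d and Card9. Cd68 of the macrophage list and RT1-Da, Ciita and Cd74 of the class II list fell just short (edgeR adjusted p = 0.0621 each). The library of vehicle rat P5 as the single source is argued against, since 16 of 16 were also called without it. Leaving out vehicle rat P14 or combination rat P23, P31 or P35 left no call, so dependence on another single library stays open. The difference of the 16 genes was also present within batch 3, at a median log2 fold change of -3.57 (median SE 0.548), against -3.69 (median SE 0.457) over both. The genes were picked in a fit that held these same libraries, so this value cannot decide whether batch added to the calls. Of the 16, 0 were among the genes near 0 in the earlier batches. The calls ended within batch 3 (smallest adjusted p 0.423, edgeR, from 0.0219), with 2 libraries fewer in the fit. They also ended with batch as a covariate (smallest adjusted p 0.105, edgeR, median log2 -3.58, median SE 0.495), where all libraries stayed. Why they ended in that fit was not tested. Of the 10 splits of the 6 libraries 1, the real one, gave 16 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05. Which leukocytes the tumours held, which were sorted and expression in each may all contribute, and no test here separates them.

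The libraries labelled DN were high in epithelial genes. The luminal list lay above each of the fibroblast, smooth muscle, endothelial and adipocyte lists by at least 2.85 log2 units in all 3. This argues against carry-over of epithelial cells into libraries made mainly of stromal cells only as far as list levels follow cell numbers. That was not tested, since levels also depend on expression per cell. A mislabelled fraction may be the source and stays open: the lowest Epcam level of the 3, by total counts, was 0.876 of that in the library labelled Ep, but that library is of another cohort, and none labelled Ep of the treated cohort could be used. Tumour cells that had lost the surface marker but kept its transcript stay open too, untested.

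In the CD45 libraries of batches 1 and 2, 97 genes had at most 3 counts, while each of the 6 CD45 libraries of batch 3 held them at 1 CPM or more. They include genes that most cells use, such as the ribosomal Rplp2 (at least 828 counts in each CD45 library of batch 3, 0 in the others), Atp5pb, Ndufa1, Chchd2, Rbm39 and Hprt1, and also Tnf and RT1-DMb. Of the 84 sets of 3 among the 9 CD45 libraries only this 1 had as many, and the highest other had 4, which is consistent with a batch difference in sequencing or counting. Which step differed stays open, and of the genes in lists Tnf and RT1-DMb are among the 97. Listed genes outside the 97 were low there too, since Pdcd1 had 0 counts in these 3 libraries and 3 to 520 in the CD45 libraries of batch 3, and RT1-DMa 1 to 6 against 226 to 4302.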
